A study of Mus musculus with 24 samples.

How the data were processed

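RNA levels were measured on 24 Affymetrix Mouse Gene 1.0 ST arrays, which carry probe sets along whole transcripts. The samples were mouse embryonic stem cells (ESCs) on day 0 and the embryoid bodies (EBs) made from them on days 3 and 7. EBs are aggregates in which ESCs differentiate. Per the labels' protocols, ESCs were expanded with LIF, a cytokine that keeps them undifferentiated, on embryonic fibroblasts (MEFs) that had been inactivated with mitomycin. EBs were started from MEF-depleted ESCs in hanging drops without LIF. Each of 4 clones was measured on 3 days with 2 arrays a day: Eed knockout (KO) cells of the lines E14 and J1, and wild-type (WT) cells of the lines J1 and V6.5. J1 and E14 come from inbred mouse strains and V6.5 from a cross of strains, so the J1 pair is the only KO and WT pair of 1 named line.

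The deposited values are log2 expression values per probe set, made by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. Tool versions, genome build and annotation are not given in the sources used here. The log base was read from the values, which ran from 2.08 to 14.4 with near-equal quartiles in all 24 columns. Such values compress differences near the background, so fold changes of weakly expressed genes are likely to be underestimates, and quantile normalization removes any change of total RNA per cell.

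Of 35556 probe sets in the table, 23410 were listed in the annotation table used here. Of these, 21789 had 1 gene symbol and entered the tests, 1621 had several symbols and were left out, and 12146 were not listed. A gene with more than 1 probe set (999 genes) was represented by the one with the highest mean over all arrays, which left 19938 genes. Gene identifiers of 21698 probe sets matched a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. No filter on low values was applied in the reported tests.

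Differences were computed with limma 3.58.1 (with statmod 1.5.0) in R 4.3.3. The linear model held 6 genotype-by-day means over all 24 arrays, with the clone as a random block because arrays of 1 clone are not independent. The consensus correlation of arrays of a clone was 0.161, and 18 residual degrees of freedom were left. Differences between KO and WT of line J1, and between lines of a genotype, came from a model of 12 line-by-genotype-by-day means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes of a comparison, and a change of at least 2-fold (1 on the log2 scale). The words higher, lower, rose and fell are used of called genes, and of lists past the same p threshold. All adjusted p-values of genes below are from limma. Standard errors (SE) are those of the model, and SD is over the 4 arrays of a genotype and day.

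The comparisons were KO against WT on each day, day 3 and day 7 against day 0 within each genotype, and the difference of these changes between genotypes (the interaction). J1 KO was also compared with J1 WT. The agreement of this pair with E14 KO against V6.5 WT, which shares no array with it, was computed across genes. Among genes that fell in WT, pluripotency genes were compared with all others by a two-sided Fisher's exact test.

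A set of 24 gene lists was tested: PRC2 components, PRC1 components, core pluripotency genes, naive pluripotency genes, primed epiblast genes, Hox genes, developmental transcription factors, primitive streak and early mesoderm, cardiac and muscle genes, blood and endothelial genes, extraembryonic and definitive endoderm, neuroectoderm and neurons, trophoblast genes, imprinted genes, germline and meiosis genes, two-cell-like genes, CDK inhibitors, p53 targets, proliferation genes, fibroblast genes (feeder cells), hypoxia and glycolysis genes, interferon response genes, proteasome subunits as a control list, and Y-linked genes. Some genes stand in several lists, among them 23 of the 81 developmental transcription factors, of which 78 were measured. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the residuals, and with fry, which asks whether the genes move one way on balance. The adjusted p of a list is over the 24 lists of a comparison.

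The genes named were set by rule. For each KO and WT comparison these were the 12 largest rises and 8 largest falls among called genes for which both KO lines lay on the same side of both WT lines, and for WT differentiation and the day 7 interaction the 6 largest each way. For J1 alone they were the 4 largest each way, and for each list up to 4 called members with the largest change, or of all members if none was called. Predicted-gene symbols were passed over, and Eed, Pou5f1, Nanog, Sox2, Zfp42, Cdkn2a and Cdkn1c were always included. Groups, tests, lists, naming and most alternatives were fixed before the data were examined. Genes named outside this scheme are marked as chosen afterwards.

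The fits were tested on simulated data with the real genes, means and spreads, in which 200 genes of 19938 changed between KO and WT on day 7. At a clone spread that varied from gene to gene, 87.5% of these were recovered: 52% at 2-fold, 98% at 2.8-fold and 100% at 4-fold and 8-fold. Of the calls, 10.7% were false, against 4.49% when the 2 arrays of a line and day were averaged. With nothing changed on day 0, 12 genes were called, and 1 with averaged arrays. With 2 lines per genotype, the number of lines limits the precision.

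Alternatives were quantile normalization of the deposited values, median centring, a filter on low values, the mean over the probe sets of a gene, no fold minimum, another variance prior, no clone block, averaging of arrays, 12 line-by-day means, a replicate block, leaving out each clone and each array, and for lists the estimated correlation and fry. Chosen after seeing the data were the leaving out of both WT J1 arrays of day 3 or of day 7, which lay far apart in some genes, the leaving out of arrays for the line comparisons, and strata of the size of the fall for the pluripotency genes.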

Results

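The data comprise 24 expression arrays of 4 ESC clones on days 0, 3 and 7, with 4 arrays per genotype and day from 2 lines of 2 arrays each. The series asks, by its title, whether EED is needed to silence pluripotency genes when ESCs differentiate. EED is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 and represses developmental genes. The labels do not say that the 2 arrays of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical. Repeat arrays of a line and day correlated at r = 0.990 or more across genes, except WT J1 on day 7 at r = 0.962. In that pair 1256 genes lay at least 2-fold apart, against 21 to 163 in the other 11 pairs.

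Eed itself (probe set 10565486) was lower in every KO array than in every WT array. On day 0 the KO arrays read 7.44 and 7.48 in E14 and 7.19 and 7.06 in J1, and the WT arrays 10.28 and 10.80 in J1 and 10.83 and 11.02 in V6.5. On day 3 the KO arrays read 5.76, 6.97, 6.21 and 6.42, and the WT arrays 9.60, 9.91, 10.25 and 10.36. On day 7 they read 6.64, 6.09, 6.26 and 6.23 in KO and 9.56, 9.41, 9.37 and 9.79 in WT. The difference was −3.44, −3.69 and −3.23 on the log2 scale on the 3 days (SE 0.226, n = 4 and 4). A second Eed probe set (10554837) had a mean of 5.76 over all arrays and was not used. The labels do not give the deleted part of the gene, so these probes show a loss of signal and not which exons are missing.

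In undifferentiated ESCs, germline genes and single Polycomb and homeobox genes were higher in KO. Mael, which silences transposons in germ cells, was 2.07 higher on the log2 scale (SE 0.285), Smc1b, a meiotic cohesin subunit, 2.17 (SE 0.309), and Tex11, a meiotic recombination gene, 1.88 (SE 0.225). The homeobox gene Meis2 was 2.09 higher (SE 0.231) and the T-box gene Tbx15 1.82 (SE 0.284). Noncoding RNAs of the imprinted Dlk1 to Dio3 region were lower: DQ267102 by −3.60 (SE 0.357), Rian by −2.23 (SE 0.311), Meg3 by −2.20 (SE 0.244), Mir377 by −1.86 (SE 0.403) and Mir380 by −1.46 (SE 0.339). Pou5f1, Nanog and Sox2, the core transcription factors of pluripotency, differed by −0.07, 0.46 and 0.04 and were not called.

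On day 0, 110 genes were called, 92 higher and 18 lower in KO, each on the same side in all pairs of lines. Other large rises were Cubn (2.12), the DNA-binding gene Radx (2.01), the oocyte gene Khdc3 (1.99), Nrk (1.88), Nxt2 (1.86), Inpp5d (1.85) and M1ap (1.75), a meiotic gene. Besides Eed and the noncoding RNAs, the largest falls were the imprinted gene Nnat (−2.11) and the axon guidance gene Ntn1 (−1.48). The germline and meiosis list had 8 of 23 measured members higher and none lower (also 8 adjusted over the list alone), among them Syce1 (1.65), Slc25a31 (1.55) and Dazl (1.34). Its median was 0.91 and its adjusted p 1.8e-21, or 0.0016 with an estimated correlation, the only list whose call held with that setting on day 0. When arrays of a line were averaged, 22 genes remained. Of the genes named, Mael (adjusted p = 0.069), Smc1b (0.072), Syce1 (0.072), Slc25a31 (0.053), Tbx15 (0.097), Rian (0.053), Ntn1 (0.075), Cubn (0.098), Inpp5d (0.097), Mir380 (0.097), Nrk (0.15), M1ap (0.16), Nnat (0.16), Mir377 (0.20) and Dazl (0.25) then lost their calls. Cubn (0.066), Nrk (0.052) and Mir380 (0.061) also lost them without WT V6.5 replicate 2, and Cubn (0.067, 0.063 and 0.055) and Mir380 (0.052, 0.058 and 0.056) without KO E14 replicate 1, KO J1 replicate 1 or WT J1 replicate 2. Leaving out a clone gave 47 genes without E14 KO, 216 without J1 KO, 272 without J1 WT and 100 without V6.5 WT. Of the 110 genes, 34, 91, 96 and 53 respectively stayed called. Leaving out WT V6.5 replicate 2 gave 71.

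Other lists shifted less on day 0. Hox genes, which pattern the body axis, had 2 of 37 higher (2 adjusted over the list alone), Hoxd13 (1.51) and Hoxd10 (1.40), with a median of 0.25 (adjusted p = 5.5e-11, but adjusted p = 0.098 with an estimated correlation). Developmental transcription factors had 2 of 78 higher, Meis2 and Tbx15 (2 adjusted over the list alone; adjusted p = 7.2e-04, and adjusted p = 0.30 with an estimated correlation). PRC1 components had 1 of 18 higher, Bmi1 at 1.65 (1 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.11 with an estimated correlation). Naive pluripotency genes had a median of 0.34 with 1 of 19 higher, Tbx3 at 1.27 (2 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.41 with an estimated correlation). Extraembryonic and definitive endoderm had 2 of 30 higher, Cubn and Dab2 (1.56), both endocytic genes (2 adjusted over the list alone; adjusted p = 0.0034, and adjusted p = 0.60 with an estimated correlation). Tbx3 and Dab2 lost their calls with averaged arrays (adjusted p = 0.39 and 0.16) and without WT V6.5 replicate 2 (0.068 and 0.11) or KO E14 replicate 1 (0.13 and 0.072). Trophoblast genes had a median of 0.14 with 0 of 18 called (0 adjusted over the list alone; adjusted p = 0.0034, and adjusted p = 0.39 with an estimated correlation), and CDK inhibitors 0.35 with 0 of 6 (0 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.11 with an estimated correlation). Among 24 core pluripotency genes none was called (0 adjusted over the list alone, adjusted p = 0.068). Of the PRC2 components, Eed alone of 11 was lower (1 adjusted over the list alone, adjusted p = 0.64). The list median was 0.04 while its mean, −0.25, and its test had the opposite sign.

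Fibroblast genes, markers of the feeder cells, were also higher in KO on day 0, with a median of 0.49 (adjusted p = 6.5e-11, and adjusted p = 0.11 with an estimated correlation). The matricellular gene Thbs1 (adjusted p = 0.042), the collagen crosslinker Lox (1.46) and the matrix gene Fbln2 (1.03) were called out of 28 (4 adjusted over the list alone), while Col1a1 (0.21), Col1a2 (0.34) and Col3a1 (0.12) were not. The list mean was 8.05 to 8.87 in the 4 KO arrays and 7.66 to 7.91 in the 4 WT arrays. Thbs1 and Fbln2 lost their calls with quantile normalization (adjusted p = 0.059 and 0.013, the latter by falling under 2-fold) and Lox with averaged arrays (adjusted p = 0.10). Without KO E14 replicate 2 all 3 lost their calls, Thbs1 with adjusted p = 0.15, Lox with 0.11 and Fbln2 at 0.90, under 2-fold.

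On day 3, KO EBs held more RNA of naive pluripotency genes, which mark the ground state of ESCs. Of 19 measured, 10 were higher and none lower (13 adjusted over the list alone), with a median of 1.39 (adjusted p = 2.6e-22, and 0.0057 with an estimated correlation). Jam2 was 2.35 higher (SE 0.416), Zfp42, an ESC marker also known as Rex1, 2.26 (SE 0.406), Tcl1, a coactivator of Akt, 2.24 (SE 0.304), and Fbxo15 1.78 (SE 0.326). Part of these differences was present on day 0, though not called. Jam2 then read 11.13 in KO and 10.22 in WT, Zfp42 11.09 and 10.4, Tcl1 10.48 and 9.54, and Fbxo15 11.02 and 10.51. The change from day 0 to day 3 differed between genotypes for 10 genes in all, and for 0 with averaged arrays. For Zfp42 on day 3, WT J1 replicate 2 read 6.04 and the other WT arrays 8.06 to 8.48. Pou5f1 (−0.12), Nanog (0.78) and Sox2 (0.18) were not called. Cdkn2a, which encodes the cell cycle inhibitor p16 and is a known Polycomb target, was 1.26 higher (SE 0.210), after 0.98 on day 0, just under 2-fold.

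In all, 151 genes were called on day 3, 133 higher and 18 lower, on the same side in all pairs of lines. The largest rises included Mael (2.86), the proteoglycan gene Srgn (2.85), Meis2 (2.59), AU015836 (2.37), the imprinted growth factor gene Igf2 (2.36), Emp1 (2.29), Pramel13 (2.27), the peptidase gene Mme (2.19) and Hoxd13 (2.14). DQ267102 (−4.85), Meg3 (−3.96), Rian (−3.35), Mir382 (−2.03), Mir377 (−1.96) and Mir380 (−1.79) were lower, as was Nnat (−1.76). With averaged arrays 43 genes were called, and Jam2 (adjusted p = 0.11), Fbxo15 (0.086), Srgn (0.087), Mme (0.078), Nnat (0.24), Mir377 (0.17) and Mir382 (0.25) lost their calls. Srgn also lost its call without most single arrays (0.11 without KO E14 replicate 2) and Mir382 without that array (0.052) or WT V6.5 replicate 1 (0.051). Without E14 KO 53 genes were called, and without J1 WT 247, of which 47 and 112 were among the 151.

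Lists of developmental regulators were higher on day 3 as well. Hox genes had 4 of 37 higher (4 adjusted over the list alone), Hoxd13, Hoxd11 (1.41), Hoxd10 (1.37) and Hoxc8 (1.29), with adjusted p = 3.5e-20, and 0.0057 with an estimated correlation. Developmental transcription factors had 3 of 78 higher (3 adjusted over the list alone), Meis2, Meis1 (2.00) and Tbx15 (1.87), with adjusted p = 1.6e-11, and 0.019 with an estimated correlation. Hoxc8 and Tbx15 lost their calls with averaged arrays (adjusted p = 0.33 and 0.086), and Hoxc8 without most single arrays (0.11 without KO E14 replicate 2). Germline and meiosis genes had 4 of 23 higher (6 adjusted over the list alone, adjusted p = 1.6e-16, and 0.0057 with an estimated correlation). CDK inhibitors, which restrain the cell cycle, had a median of 0.58 with Cdkn2a alone called of 6 (1 adjusted over the list alone; adjusted p = 0.0015, and 0.019 with an estimated correlation), but adjusted p = 0.079 without J1 WT.

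The remaining shifts of day 3 rested on the preset correlation. Core pluripotency genes had 2 of 24 higher, Dnmt3l (2.08), a cofactor of DNA methylation, and Gdf3 (1.01) (3 adjusted over the list alone; adjusted p = 1.9e-04, and adjusted p = 0.36 with an estimated correlation). Trophoblast genes had 2 of 18 higher, Peg10 (1.40) and Tfap2c (1.18) (3 adjusted over the list alone; adjusted p = 5.7e-06, and adjusted p = 0.12 with an estimated correlation). Extraembryonic and definitive endoderm had a median of 0.42 and 2 of 30 higher, Cubn (1.87) and Lama1 (1.10) (2 adjusted over the list alone; adjusted p = 4.6e-05, and adjusted p = 0.36 with an estimated correlation). Dnmt3l (adjusted p = 0.077), Peg10 (0.090), Gdf3 (0.26), Tfap2c (0.33), Cubn (0.14) and Lama1 (0.25) lost their calls with averaged arrays. Gdf3, Tfap2c, Cubn and Lama1 also lost them without KO E14 replicate 2 (0.076, 0.16, 0.073 and 0.13), among other single arrays. Primed epiblast genes, which mark the next stage of development, were lower with a median of −0.53 and 0 of 12 called (1 lower adjusted over the list alone; adjusted p = 2.7e-04, and adjusted p = 0.31 with an estimated correlation). Imprinted genes had 6 of 31 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.36 with an estimated correlation). Fibroblast genes had a median of 0.20 with 0 of 28 called (1 adjusted over the list alone; adjusted p = 6.1e-04, and adjusted p = 0.40 with an estimated correlation). The control list of 31 proteasome subunits had a median of −0.15 on day 0 and −0.12 on day 3 with 0 called (0 adjusted over the list alone). It too passed the threshold (adjusted p = 1.9e-04 on both days), and did not with an estimated correlation (adjusted p = 0.11 on day 0 and adjusted p = 0.12 on day 3).

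On day 7, pluripotency genes stayed high in KO EBs and the globin genes of primitive blood stayed low. Pou5f1 read 11.80 ± 0.22 in KO and 8.68 ± 0.49 in WT (SD, n = 4 and 4), a difference of 3.12 (SE 0.176, adjusted p = 1.4e-11). Nanog read 12.33 ± 0.44 against 8.77 ± 0.73 (3.56, SE 0.325), Sox2 11.49 ± 0.29 against 9.04 ± 1.29 (2.45, SE 0.405) and Zfp42 10.12 ± 0.31 against 6.01 ± 0.41 (4.11, SE 0.406). The embryonic globins Hbb-bh1, Hbb-y and Hba-x were lower by −7.40 (SE 0.323), −6.61 (SE 0.282) and −5.79 (SE 0.251). Cdkn2a was 1.79 higher (SE 0.210), while Cdkn1c, another CDK inhibitor, differed by −0.07 and was not called.

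**Figure D1:**
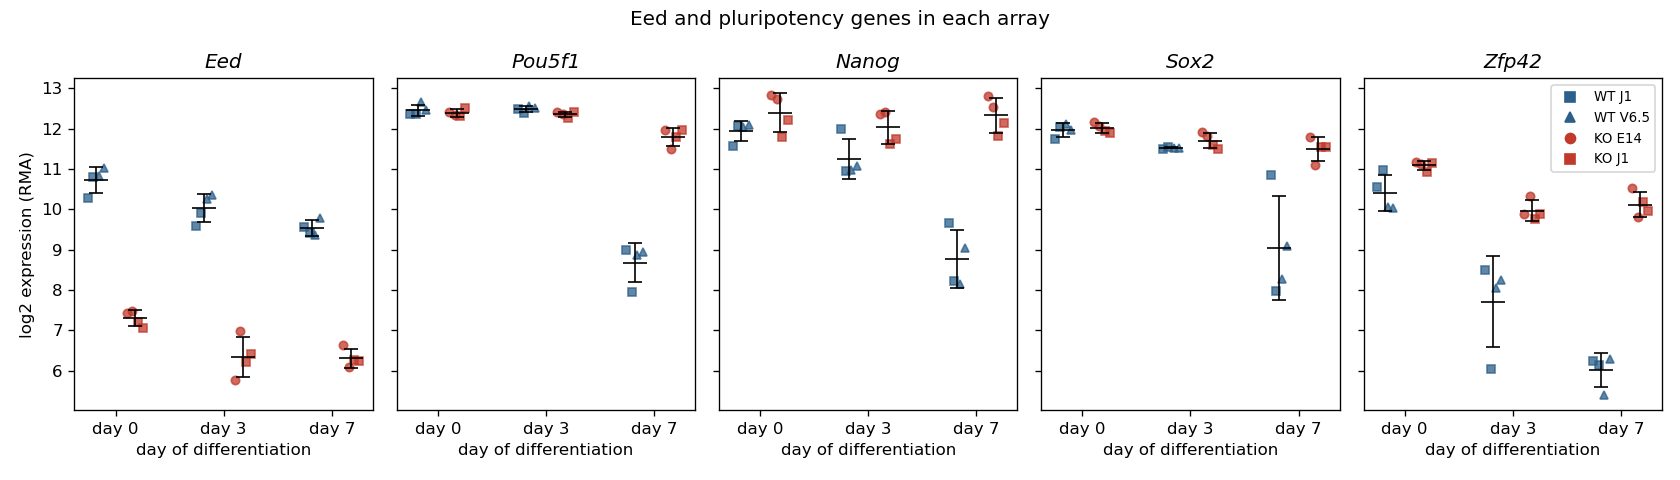
Log2 expression of Eed and of 4 pluripotency genes in each of the 24 arrays by day, with WT in blue, KO in red and the line given by the marker; black bars show the mean ± SD of the 4 arrays of a genotype and day. All KO arrays lie below all WT arrays for Eed, and all KO arrays lie above all WT arrays on day 7 for Pou5f1, Nanog, Sox2 and Zfp42.

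Day 7 had 870 called genes, 615 higher and 255 lower in KO, of which 864 lay on the same side in all pairs of lines. Core pluripotency genes had 19 of 24 higher and none lower (19 adjusted over the list alone), among them Dppa2 (4.29, SE 0.220), Dnmt3l (4.23, SE 0.338) and the Nodal antagonist Lefty2 (3.42, SE 0.341). The list median was 2.35 (adjusted p = 6.4e-31, and 0.0035 with an estimated correlation). Naive pluripotency genes had 15 of 19 higher (15 adjusted over the list alone), led by the nuclear receptor gene Nr0b1 (5.00, SE 0.452), Dppa5a (4.27, SE 0.274) and Fbxo15 (3.97, SE 0.326), with a median of 2.32 (adjusted p = 5.6e-22, and 0.0063 with an estimated correlation). Germline and meiosis genes had 12 of 23 higher (12 adjusted over the list alone), with Mael at 3.94 (SE 0.285), Dazl at 2.54, Rnf17 at 2.54 and Sycp3 at 2.25 (median 1.57, adjusted p = 2.7e-20, and 0.0026 with an estimated correlation). Further large rises were the zinc finger genes Zfp980 (4.69) and Zfp640 (4.22), Tcl1 (3.82), Srgn (3.79) and AU018091 (3.78). The count stayed within 1.5 times under every alternative but 1: without a fold minimum 3250 genes were called. The genes themselves changed more than the count. Of the 870, 628 stayed called without E14 KO, 724 without J1 KO, 786 without J1 WT and 633 without V6.5 WT.

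Blood and endothelial genes were lower in KO on day 7, with 13 of 25 called lower and none higher (14 adjusted over the list alone). Kdr, the VEGF receptor of blood and vessel progenitors, was lower by −2.23 (SE 0.451). The list median was −1.16 (adjusted p = 1.2e-12, and adjusted p = 0.19 with an estimated correlation). Alas2, the heme synthesis enzyme of red blood cells, was lower by −3.66 (SE 0.419) and the liver enzyme gene Tdo2 by −3.72 (SE 0.449). Cardiac and muscle genes had 6 of 23 lower (6 adjusted over the list alone), among them Tbx20 (−2.80), Tnni1 (−2.15), Actc1 (−1.77) and Mef2c (−1.58), with adjusted p = 1.4e-04, and adjusted p = 0.39 with an estimated correlation. Primitive streak and early mesoderm had 3 of 19 lower, Foxf1 (−2.95), Hand1 (−2.56) and Kdr, and 1 higher, Tcf15 at 1.38 (3 and 1 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.42 with an estimated correlation). Its call was also lost with averaged arrays (0.076), without E14 KO (0.061), and without WT J1 replicate 1 (0.073), KO E14 replicate 1 (0.059) or WT V6.5 replicate 2 (0.062). Kdr lost its own call with averaged arrays (adjusted p = 0.058).

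Some Hox genes were higher in KO on day 7. Of 37 10 were higher and 1 lower (10 and 1 adjusted over the list alone), with Hoxd13 at 2.66 (SE 0.199), Hoxd11 at 2.20, Hoxd10 at 2.14 and Hoxa11 at 2.03. The list passed with adjusted p = 5.5e-09, and not with an estimated correlation (adjusted p = 0.11). Developmental transcription factors went both ways, 5 of 78 higher and 6 lower (5 and 6 adjusted over the list alone, adjusted p = 0.94), with a median of 0.03 and a mean of −0.03. Trophoblast genes had 6 of 18 higher, among them Rhox9 (2.88), Krt7 (2.04) and Syna (1.88), and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.061). Imprinted genes had 1 of 31 higher, the Polycomb-related Sfmbt2 (2.08), and 3 lower, Meg3 (−4.61, SE 0.244), Rian (−3.35) and Nnat (−1.68) (1 and 3 adjusted over the list alone, adjusted p = 0.18). DQ267102 (−4.66) and Mir377 (−3.48) of the same region as Meg3 were lower too. Syna and Nnat lost their calls with averaged arrays (adjusted p = 0.13 and 0.067).

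Polycomb genes besides Eed also differed on day 7. PRC1 components had 3 of 18 higher, Phc1 (1.35, SE 0.165), Bmi1 (1.23, SE 0.197) and Cbx7 (1.04, SE 0.201) (3 adjusted over the list alone, adjusted p = 0.19). Among PRC2 components the accessory subunit gene Jarid2 was 1.16 higher (SE 0.153) and Eed lower (1 and 1 of 11 adjusted over the list alone, adjusted p = 0.19). CDK inhibitors had 2 of 6 higher, Cdkn2a and Cdkn2b at 1.08 (2 adjusted over the list alone, adjusted p = 0.061, and fry's adjusted p = 1.2e-04). Cbx7 fell under 2-fold without KO J1 replicate 2 or WT J1 replicate 1, and Cdkn2b without KO E14 replicate 1.

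**Figure D2:**
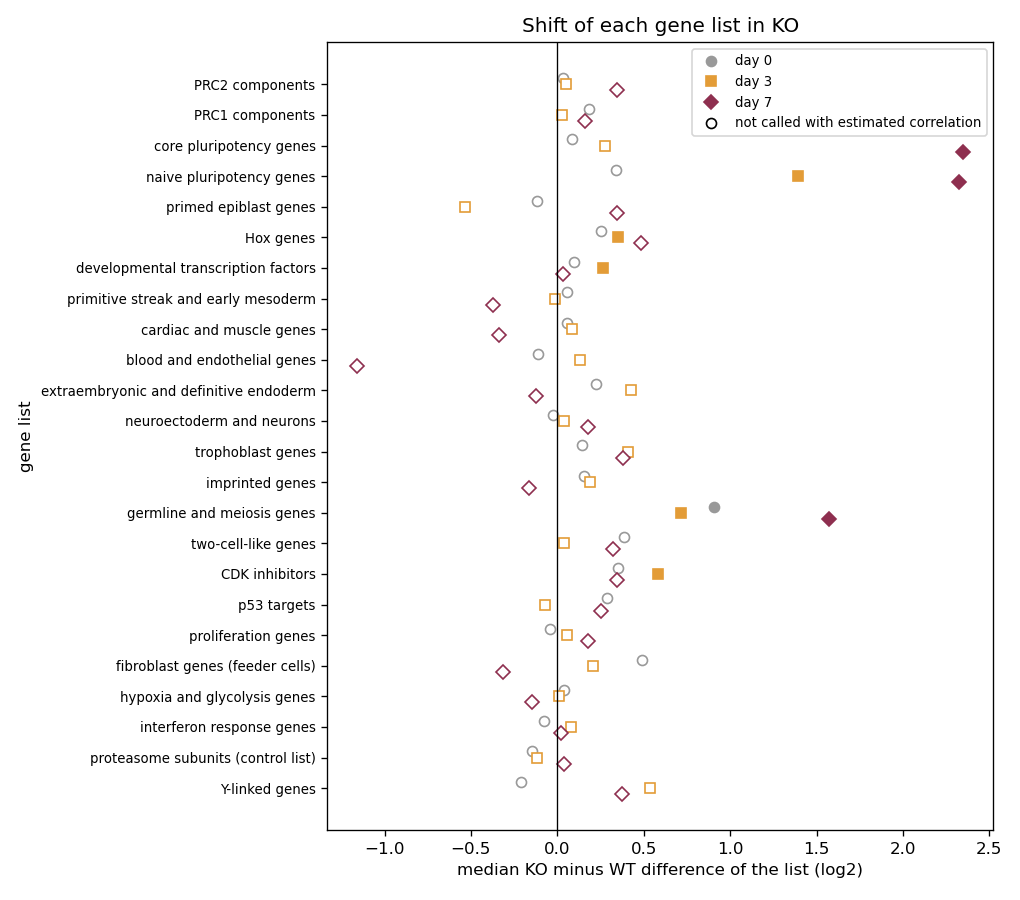
Median KO minus WT difference of each of the 24 gene lists on the log2 scale, on day 0 (circles), day 3 (squares) and day 7 (diamonds); filled symbols mark lists whose adjusted p stayed under 0.05 with an estimated correlation. Core and naive pluripotency genes reach medians of 2.35 and 2.32 on day 7, and blood and endothelial genes lie at −1.16.

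WT cells left the naive state within 3 days. From day 0 to day 3, 18 of 19 naive pluripotency genes fell in WT (18 adjusted over the list alone), with a median of −1.82 (adjusted p = 1.1e-26, and 0.0070 with an estimated correlation). Fbxo15 (−2.71, SE 0.277) and Zfp42 (−2.70, SE 0.345) were among them. Fgf5, the classic marker of the primed epiblast, rose by 2.72 (SE 0.306) and Sall2 by 2.41 (SE 0.289). Primed epiblast genes had 5 of 12 risen (6 adjusted over the list alone), with adjusted p = 6.3e-09, and adjusted p = 0.15 with an estimated correlation. Calcr (2.54) and the microRNA genes Mir302a (2.58), Mir302d (2.36) and Mir302c (2.36) rose, and Socs3, a target of LIF signalling, fell by 2.67 on the log2 scale, Emp1 by 3.05, the noncoding RNA Platr8 by 2.70 and the matrix gene Bgn by 2.95. In all 407 genes changed in WT by day 3, 191 up and 216 down. Fibroblast genes had 5 of 28 fallen in WT over these days, after MEF depletion (5 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.64 with an estimated correlation).

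KO cells changed in the same direction at fewer called genes, 233 by day 3, 112 up and 121 down. Naive pluripotency genes had 6 of 19 fallen in KO (8 adjusted over the list alone), among them Klf4 (−1.86, SE 0.295) and Fbxo15 (−1.43, SE 0.277), with a median of −0.85 (adjusted p = 2.8e-12, and adjusted p = 0.088 with an estimated correlation). Fgf5 rose by 2.23 (SE 0.306) and Sall2 by 1.49 (SE 0.289). Of the 191 genes that rose in WT, 68 were called in KO, where 1.07 would overlap if the calls were independent, and of the 216 that fell, 68, where 1.31 would. Without E14 KO, 124 genes changed in KO by day 3. The difference between genotypes in the change to day 3 was called for 10 genes, 6 more positive and 4 more negative in KO, and 1066 genes passed an unadjusted p under 0.05. Meg3 (−1.76), Khdc3 (−1.58) and Ntn1 (1.58) were among the 10, chosen after their values were seen. This count was 0 with averaged arrays and 24 without J1 WT, and fell to 4 without KO E14 replicate 1 of day 0.

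By day 7 embryonic globin genes had risen in WT EBs, and most pluripotency genes had fallen. Hbb-bh1 rose by 7.43 (SE 0.275), Hbb-y by 6.83 (SE 0.240) and Hba-x by 5.82 (SE 0.214). The VEGF and semaphorin coreceptor Nrp1 rose by 5.52 (SE 0.308), Bmp5 by 4.62 (SE 0.273) and the yolk sac and liver gene Ttr by 4.62 (SE 0.644). Nr0b1 changed by −5.62 (SE 0.384), Platr8 by −4.55, Zfp980 by −4.52, Dnmt3l by −4.47, Fbxo15 by −4.41 and Zfp42 by −4.39. Core pluripotency genes had 20 of 24 fallen (20 adjusted over the list alone; adjusted p = 3.1e-22, and 0.029 with an estimated correlation) and naive pluripotency genes 16 of 19 (16 adjusted over the list alone; adjusted p = 5.4e-14, and 0.040 with an estimated correlation). Imprinted genes had 15 of 31 risen (15 adjusted over the list alone), among them Igf2 (4.12), Airn (3.91) and Dlk1 (3.41), with adjusted p = 5.4e-09, and 0.029 with an estimated correlation. Blood and endothelial genes had 17 of 25 risen (17 adjusted over the list alone; adjusted p = 5.1e-12, and adjusted p = 0.17 with an estimated correlation). Extraembryonic and definitive endoderm had 15 of 30 risen and 1 fallen (15 and 1 adjusted over the list alone; adjusted p = 2.2e-07, and adjusted p = 0.19 with an estimated correlation). In WT 1791 genes changed, 1015 up and 776 down.

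In KO, 492 genes changed by day 7, 408 up and 84 down. Imprinted genes had 11 of 31 risen in KO (11 adjusted over the list alone), with Dlk1 at 3.38 (SE 0.247), Airn at 2.99, Igf2 at 2.83 and Peg3 at 2.67 (adjusted p = 4.0e-13, and 0.0089 with an estimated correlation). Hox genes had 7 of 37 risen (7 adjusted over the list alone; adjusted p = 4.5e-19, and 0.010 with an estimated correlation), and trophoblast genes 8 of 18, among them Plac1 (2.74) and Krt8 (2.38) (8 adjusted over the list alone; adjusted p = 5.8e-08, and adjusted p = 0.088 with an estimated correlation). Of 42 pluripotency genes measured over the core and naive lists together, 35 had fallen in WT and 2 in KO, Utf1 (−1.08) and Klf4 (−1.23). Pou5f1 changed by −0.59 (SE 0.150), Nanog by −0.07 and Sox2 by −0.52 in KO, none of them called. The 2-fold minimum weighs on this contrast. In KO, Pou5f1 (adjusted p = 0.0077), Klf5 (−0.94, 0.0019), L1td1 (−0.83, 1.0e-04) and Foxd3 (−0.93, 1.2e-04) passed the p threshold with changes under 2-fold. So did falls of Tet1, Stat3, Gbx2, Mycn, Dppa4, Lin28a, Fbxo15, Fgf4, Gdf3, Dnmt3l, Mybl2, Trim28 and Lefty2. Their adjusted p ran from 4.6e-04 (Tet1) to 0.041 (Lefty2). Many pluripotency genes thus fell detectably in KO, though by less than 2-fold. Nanog (0.92) and Sox2 (0.36) did not pass. Klf5, L1td1, Foxd3 and the genes from Tet1 to Lefty2 were chosen here after their values were seen. Genes that rose in WT had a median change of 1.45 in WT and 0.73 in KO. Of these, 284 (28.0%) were called in KO, where 20.8 would overlap if the calls were independent. Genes that fell in WT had a median of −1.33 in WT and −0.51 in KO. Of these, 62 (7.99%) were called in KO, where 3.27 would overlap. The genes were picked by their call in WT, which by itself makes the WT medians larger than those of KO.

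**Figure D3:**
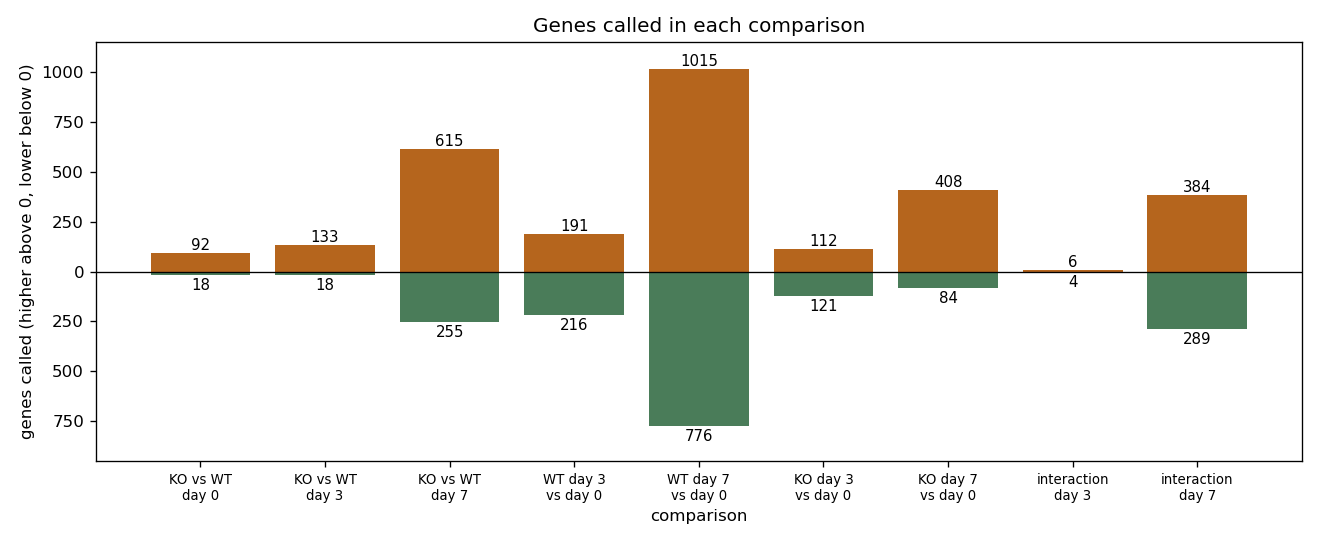
Number of genes called in each comparison, with genes higher (or risen) above 0 and genes lower (or fallen) below 0. WT EBs had 776 fallen genes on day 7 and KO EBs 84.

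The change from day 0 to day 7 differed between genotypes for 673 genes, 384 more positive and 289 more negative in KO. Of the 776 genes that fell in WT, 306 fell less in KO, and of the 1015 that rose, 262 rose less. The interaction was 5.05 for Nr0b1 (SE 0.544), 4.09 for Zfp980, 3.89 for the ESC noncoding RNA Lncenc1, 3.80 for Dppa2, 3.69 for Serpinb9e and 3.64 for Dppa5a. It was 3.19 for Pou5f1 (SE 0.212), 3.10 for Nanog, 2.41 for Sox2 and 3.42 for Zfp42. On the other side stood Hbb-bh1 (−6.84, SE 0.389), Hbb-y (−6.50), Hba-x (−5.54), the smooth muscle actin gene Acta2 (−4.81), the matrix gene Postn (−4.07) and Tbx20 (−3.89). Acta2 and Postn belong to the fibroblast list and differed by 1.57 and 1.82 on day 0, not called, and by −3.24 and −2.25 on day 7. Part of their interaction is thus the day 0 difference. Core pluripotency genes had 18 of 24 and naive pluripotency genes 14 of 19 called, all less reduced in KO (18 and 14 adjusted over the list alone), with adjusted p = 3.4e-33 and 7.7e-19, and 0.0048 and 0.019 with an estimated correlation. Among blood and endothelial genes 10 of 25 rose less (11 adjusted over the list alone; adjusted p = 3.8e-15, and adjusted p = 0.14 with an estimated correlation), and cardiac and muscle genes 6 of 23 (6 adjusted over the list alone; adjusted p = 5.2e-07, and adjusted p = 0.14 with an estimated correlation). Serpinb9e lost its call with averaged arrays (adjusted p = 0.11). The count was 371 without E14 KO (264 more positive and 107 more negative in KO), 1013 without J1 WT (451 and 562) and 313 without V6.5 WT (238 and 75), so the balance of directions depended on which lines were used. Of the 673 genes, 322, 602 and 263 respectively stayed called.

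The title speaks of selective silencing, so pluripotency genes were compared with the other genes that fell in WT. Of the 35 pluripotency genes that fell, 33 (94.3%) were higher in KO than in WT on day 7, against 309 of 741 other fallen genes (41.7%), an odds ratio of 23.0 (95% interval 5.81 to 199, two-sided Fisher's exact p = 1.5e-10). By the interaction these were 31 (88.6%) against 275 (37.1%), an odds ratio of 13.1 (4.56 to 51.6, Fisher's exact p = 1.0e-09). Single arrays moved these odds ratios, while p stayed under 0.05. The first was 13.3 without WT J1 day 7 replicate 2, 15.2 without WT J1 day 7 replicate 1 and 14 without KO J1 day 7 replicate 1. By the interaction it was 7.43 without WT J1 day 7 replicate 2, and 8.34 and 8.20 without WT V6.5 day 0 replicate 1 or 2. The pluripotency genes had also fallen further in WT, by a median of −3.07 against −1.30. Within 5 strata of the size of the WT fall, chosen after seeing the data, the common odds ratio was 4.87 (1.05 to 46.4, exact p = 0.032), and by the interaction 2.42 (0.73 to 10.7, exact p = 0.15), which is not past the threshold. Among the genes that fell most, 27 of 28 pluripotency genes and 115 of 128 others (89.8%) were higher in KO. The fall in WT and the difference from KO use the same WT arrays of day 7, which raises both shares, and genes are not independent replicates.

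**Figure D4:**
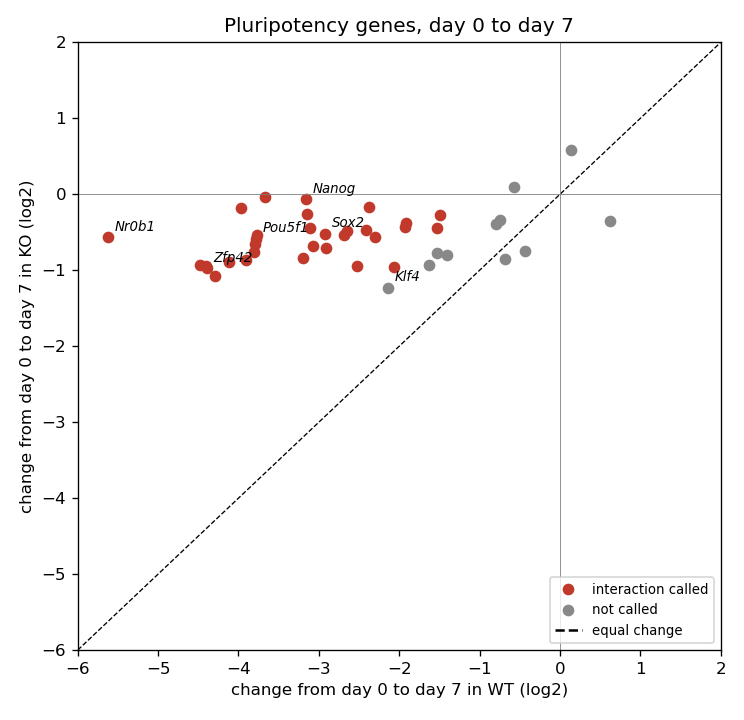
Change from day 0 to day 7 of the 42 measured pluripotency genes in WT (horizontal) and KO (vertical) on the log2 scale, with genes called in the interaction in red, other genes in grey and equal change on the dashed line. Called falls, of at least 2-fold, numbered 35 in WT and 2 in KO. Many smaller KO falls, under 2-fold, also passed the p threshold.

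Within the J1 line alone, where KO and WT share a name and background, Pou5f1 was 3.41 higher in KO on day 7 (SE 0.222), Nanog 3.04 (SE 0.372), Sox2 2.14 (SE 0.523) and Zfp42 3.89 (SE 0.475). The largest differences that day were Nr0b1 (5.39), Zfp980 (5.33), Dnmt3l (4.62), Zfp640 (4.59), Hbb-bh1 (−6.88), Hbb-y (−6.38), Hba-x (−5.41) and DQ267102 (−4.85). On day 0 Cubn (2.49), the PRC1 gene Bmi1 (2.03), Meis2 (1.99) and Khdc3 (1.85) were higher, and DQ267102 (−3.65), Nnat (−3.52), Eed (−3.41) and Gbp2b (−2.46) lower. On day 3 AU015836 (3.08), Zfp640 (2.86), Zfp980 (2.84) and Mael (2.67) were higher, and DQ267102 (−5.20), Meg3 (−3.82), Eed (−3.44) and Rian (−3.24) lower. Called were 91, 200 and 857 genes on days 0, 3 and 7. These counts rest on 2 arrays a group: without KO J1 replicate 2 they were 50 and 73 on days 0 and 3, on day 3 also 335 without WT J1 replicate 1 and 82 without replicate 2. On day 7, leaving out WT J1 replicate 1 gave 1651, and a fit of the 4 J1 arrays of that day alone 120. Sox2 lost its call in J1 on day 7 without WT J1 replicate 2 (adjusted p = 0.097) or without a KO J1 array (0.056 and 0.069). The WT J1 arrays of that day read 10.84 and 7.97 for Sox2.

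The J1 pair and the pair of E14 KO and V6.5 WT share no array, and their differences correlated across genes at r = 0.37, 0.39 and 0.63 on days 0, 3 and 7 (Spearman's rho 0.25, 0.21 and 0.44), where genes are not independent replicates. Of genes called in J1, 80.2%, 90.5% and 95.6% had the same direction in the other pair. On day 7, 364 genes were called higher in both pairs, where 26.0 would overlap if the calls were independent, and 125 lower in both, where 6.08 would. Lines of a genotype differed as well: E14 KO and J1 KO at 79, 9 and 199 genes on days 0, 3 and 7, and V6.5 WT and J1 WT at 190, 127 and 198. Single arrays moved these line counts, to between 14 and 77, 1 and 27, and 115 and 211 for KO and between 93 and 153, 59 and 225, and 121 and 787 for WT when each array was left out.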

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

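Chosen only after the result was seen were the tests of residual day 0 cells and of cell line background for pluripotency genes, and the strata of fall size were also added after the data were seen, with a prediction written before their own result. All splits of arrays and lines were set out before their results were seen.

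Single arrays stood far from the other 3 of their group in 5 of 42 groups tested of the 7 always named genes, where chance gives about 1 in 20. Pou5f1 on day 7 read 7.95 in WT J1 replicate 2 and 8.86 to 8.98 in the other WT arrays. Nanog read 11.56 in WT J1 replicate 1 on day 0 against 12.03 to 12.08, and 12 in WT J1 replicate 1 on day 3 against 10.96 to 11.06. Zfp42 read 5.40 in WT V6.5 replicate 1 on day 7 against 6.15 to 6.28. Cdkn1c read 9.32 in KO E14 replicate 1 on day 3 against 9.08 to 9.12. Of these 5 arrays 3 are WT J1, the clone whose replicates lay furthest apart on day 7. Larger distances on the log2 scale occurred outside these 5 groups, chosen here after their values were seen. Zfp42 read 6.04 in WT J1 replicate 2 on day 3 against 8.06 to 8.48 in the other WT arrays. Sox2 read 10.84 in WT J1 replicate 1 on day 7 against 7.97 to 9.09.

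The change from day 0 differed between KO and WT for 10 genes by day 3 and 673 by day 7. By day 7 this difference was 3.19 for Pou5f1, 3.10 for Nanog, 2.41 for Sox2, 3.42 for Zfp42, 5.05 for Nr0b1, 4.09 for Zfp980, 3.89 for Lncenc1, 3.80 for Dppa2, 3.69 for Serpinb9e and 3.64 for Dppa5a. It was −6.84 for Hbb-bh1, −6.50 for Hbb-y, −5.54 for Hba-x, −4.81 for Acta2, −4.07 for Postn and −3.89 for Tbx20. The genotype was drawn anew within each day, in a fit without the clone block and on the arrays of day 0 and the later day alone. The real genotypes gave 6 genes by day 3 and 462 by day 7 in this fit, other counts than in the fits over all arrays. Of 100 labellings, the real one among them, 5 called at least 6 genes by day 3, with up to 340 in the others, so chance is not excluded there. By day 7, 4 of 100 called at least 462, with up to 961 in the others. This is under 1 in 20, but 100 labellings cannot tell 4 from 5, so chance is not excluded by day 7 either. Draws that mix genotypes on some days and not on others carry the genotype difference itself into the change. Whether the large counts came from such draws was not tested.

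For the simple comparisons, all 35 splits of 8 arrays into 4 and 4 were counted without the clone block, and in each case 1 split, the real one, reached the real count. KO against WT called 129 genes on day 0 (highest other split 15), 192 on day 3 (1) and 740 on day 7 (0). WT changes called 381 genes by day 3 (71) and 1723 by day 7 (3), and KO changes 244 (18) and 461 (28). The other splits mix the 2 real groups, which raises their spread and lowers their counts. They also take arrays as independent, which arrays of a clone are not, so these counts do not exclude chance. Lines are the stricter unit, and 4 lines give 3 splits, too few for a share under 0.05, with 110 genes against a highest other of 4 on day 0, 151 against 0 on day 3 and 870 against 2 on day 7 (1 split of 3 each time, the real one).

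For the pluripotency genes that stayed high in KO on day 7, background of the cell lines is argued against, since the median difference within J1 alone was 2.16 (list means of 10.2 and 10.3 in the J1 KO arrays and 8.14 and 7.85 in the J1 WT arrays). A share of KO cells that kept the day 0 profile remains open. The share kept was taken, on the unlogged scale, of the distance between the day 7 level of WT and the day 0 level of the KO line. KO arrays kept a median of 58.3% (SD 11.4, n = 4) at pluripotency genes, 52.7% (SD 7.73) at other fallen genes and 62.8% (SD 9.99) at risen genes. These medians leave out genes whose day 0 level in the KO line was not at least 2-fold above (fallen genes) or below (risen genes) the WT level on day 7: 34 (E14) and 35 (J1) of 35 pluripotency genes were used, 514 and 593 of 741 other fallen genes and 763 and 864 of 1015 risen genes. The first 2 shares differed by a mean of 5.55 points (SD 8.66, with 8.79, 15.8, −4.33 and 1.99 in single arrays). Unchanged cells alone would keep 1 share at every gene, which medians over 4 arrays of 2 clones hardly test. Risen genes kept more than other fallen genes in each array (72.2, 61.7, 49.3 and 68.0% against 57.6, 46.5, 45.8 and 61.0%). Single genes, chosen after their values were seen, differed. In KO, Nanog read 12.39 on day 0 and 12.33 on day 7 (WT 8.77 on day 7), and Klf4 10.95 and 9.71 (WT 8.38). Larger falls of pluripotency genes in WT, which pass the threshold more easily, cannot be told apart from selectivity: within strata of fall size the odds ratio was 4.87 with a lower bound of 1.05, but by the interaction the interval included 1, and 28 of the 35 genes lay in the open-ended stratum of largest falls. The loss of Eed itself, the biological difference in the design, stays open, whether it acts on these genes or on how many cells differentiate.

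The KO minus WT difference differed between the J1 pair and the pair of E14 KO and V6.5 WT for 166 genes on day 0, 101 on day 3 and 468 on day 7. Of these, 15, 3 and 126 respectively were also called in KO against WT.

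Probe sets without a single gene symbol (13767), which no comparison used, were called in KO against WT 16 times on day 0 (9 higher), 24 times on day 3 (12 higher) and 245 times on day 7 (142 higher).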

How the results depend on the processing

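Chosen after seeing the data were the tests without both WT J1 arrays of day 3 or day 7, the leaving out of arrays for line comparisons, and the strata of fall size. Where values changed, the cause was not tested, except that without a fold minimum more genes can pass by construction. Results of single genes were compared under 6 alternatives, and 0 reversed direction there; the others were run for counts, lists and other summaries and not for single genes. Of 514 gene results with 315 calls, quantile normalization ended 5 calls, a replicate block 5, and leaving out single arrays 40, while adding 11. Of 471 with 283 calls, averaging of arrays ended 61 and no clone block 6, and of 262 with 141 calls J1 alone ended 31. Deviations of replicate 1 from replicate 2 correlated across genes at r of −0.40 to 0.47 over all 66 pairs of groups, with a median of 0.06. Between clones of 1 day (18 pairs) the median was 0.05, with 6 over 0.1 and a lowest value of −0.40, so replicate numbers showed no pairing common to all clones. The KO clones correlated at 0.12, 0.25 and 0.14 on days 0, 3 and 7, so a link between these is not excluded. Across genotypes, KO J1 and WT J1 correlated at 0.43, −0.17 and −0.15 on these days, and KO E14 and WT V6.5 at 0.02, 0.29 and −0.02. A link between KO and WT arrays on single days is therefore not excluded either. Between days of 1 clone (12 pairs) the median was 0.22, with 8 over 0.1 and a highest value of 0.47, so a link between days of a clone is not excluded. A replicate block changed 0 list calls and gave 105, 143 and 864 genes for KO against WT on days 0, 3 and 7.

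Without a fold minimum the counts were 402, 434 and 3250 for KO against WT on days 0, 3 and 7, and 331, 519 and 2840 within J1. They were 2324 and 7301 for WT by days 3 and 7, 1269 and 3299 for KO, and 1617 for the interaction on day 7. Line differences then numbered 302, 50 and 651 in KO and 605, 507 and 804 in WT. With averaged arrays KO against WT gave 22 genes on day 0 and 43 on day 3, all among those called with single arrays, and 751 of the 870 genes of day 7 stayed called. On day 0 there were 47 genes without E14 KO, 216 without J1 KO and 272 without J1 WT, and on day 3 there were 53 without E14 KO and 247 without J1 WT. KO changes by day 3 numbered 124 without E14 KO. The interaction by day 3, 10 genes, gave 21 with 12 line-by-day means, 0 with averaged arrays, 5 without a clone block, 5 without both WT J1 arrays of day 3, 1 without E14 KO, 4 without J1 KO, 24 without J1 WT and 6 without V6.5 WT. By day 7 it gave 371 without E14 KO (264 more positive and 107 more negative in KO), 1013 without J1 WT (451 and 562) and 313 without V6.5 WT (238 and 75), against 384 and 289 with all lines. Within J1 on day 7, the 4 arrays of that day alone gave 120 genes. The odds ratio of pluripotency genes against other fallen genes ran from 13.3 (without WT J1 day 7 replicate 2) to 25.3 when each array was left out, and by the interaction from 7.43 (without the same array) to 14.2. By the interaction it was 2.42 within 5 strata of fall size, and not past the threshold.

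Leaving out each array moved the count of KO against WT on day 0 between 71 (without WT V6.5 replicate 2) and 122, and the interaction by day 3 between 4 (without KO E14 replicate 1 of day 0) and 14. Within J1 the counts ran from 50 (without KO J1 replicate 2) to 78 on day 0, from 73 (without KO J1 replicate 2) to 335 (without WT J1 replicate 1) on day 3, and from 634 to 1651 (without WT J1 replicate 1) on day 7. Line differences in KO ran from 14 (without E14 replicate 2) to 77, from 1 (without E14 replicate 2) to 27 (without E14 replicate 1) and from 115 (without J1 replicate 2) to 211 on the 3 days. In WT they ran from 93 (without V6.5 replicate 1) to 153, from 59 (without V6.5 replicate 2) to 225 (without J1 replicate 1) and from 121 (without V6.5 replicate 2) to 787 (without J1 replicate 2). The correlation of the line pairs across genes ran from 0.313 to 0.390, from 0.311 to 0.439 and from 0.550 to 0.647.

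Gene lists past the threshold in 1 setting and not in another follow, with the adjusted p of KO against WT in parentheses. Germline and meiosis genes on all 3 days, naive pluripotency genes, Hox genes and developmental transcription factors on day 3, and core and naive pluripotency genes on day 7 kept their calls under every alternative run for lists.

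With the estimated correlation, CDK inhibitors (0.106), developmental transcription factors (0.297), extraembryonic and definitive endoderm (0.598) and fibroblast genes (0.106) lost their call on day 0. On day 0 the lists Hox genes (0.0976), naive pluripotency genes (0.414), p53 targets (0.467) and PRC1 components (0.106) lost their call. Proteasome subunits (0.106), trophoblast genes (0.386) and two-cell-like genes (0.363) lost their call on day 0. On day 3 the lists core pluripotency genes (0.361), extraembryonic and definitive endoderm (0.361), fibroblast genes (0.397) and imprinted genes (0.361) lost their call. Primed epiblast genes (0.306), proteasome subunits (0.115) and trophoblast genes (0.115) lost their call on day 3. On day 7 the lists blood and endothelial genes (0.186), cardiac and muscle genes (0.386), Hox genes (0.105) and primitive streak and early mesoderm (0.417) lost their call.

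By fry, developmental transcription factors (0.145), extraembryonic and definitive endoderm (0.505), naive pluripotency genes (0.305) and p53 targets (0.328) lost their call on day 0. On day 0 the lists trophoblast genes (0.238) and two-cell-like genes (0.175) lost their call. Core pluripotency genes (0.172), extraembryonic and definitive endoderm (0.218), fibroblast genes (0.224) and imprinted genes (0.324) lost their call on day 3. Primed epiblast genes (0.169) lost their call on day 3. PRC2 components (0.0385) gained a call on day 0. On day 7 the lists CDK inhibitors (1.21e-04), imprinted genes (0.0495) and PRC1 components (0.00719) gained a call.

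With averaged arrays, primitive streak and early mesoderm (0.0756) lost its call on day 7. Core pluripotency genes (0.0488) gained a call on day 0. Cardiac and muscle genes (0.0289) gained a call on day 3. On day 7 the lists neuroectoderm and neurons (0.0302) and proliferation genes (0.0302) gained a call.

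Without E14 KO, naive pluripotency genes (0.0809), trophoblast genes (0.0851) and two-cell-like genes (0.925) lost their call on day 0. Imprinted genes (0.132) lost its call on day 3. Primitive streak and early mesoderm (0.0606) lost its call on day 7. Core pluripotency genes (0.0407) gained a call on day 0. Blood and endothelial genes (0.00193) and p53 targets (3.40e-04) gained a call on day 3. On day 7 the lists extraembryonic and definitive endoderm (0.0435), imprinted genes (0.0282), primed epiblast genes (0.0343) and proliferation genes (0.00210) gained a call.

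Without J1 KO, p53 targets (0.0972) and PRC1 components (0.0889) lost their call on day 0. On day 3 the lists cardiac and muscle genes (0.0489) and hypoxia and glycolysis genes (0.0123) gained a call. CDK inhibitors (0.0219), fibroblast genes (0.0220), interferon response genes (0.0414) and p53 targets (4.79e-05) gained a call on day 7. On day 7 the lists trophoblast genes (4.79e-05) and two-cell-like genes (9.18e-04) gained a call.

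Without J1 WT, CDK inhibitors (0.186), naive pluripotency genes (0.146) and PRC1 components (0.0756) lost their call on day 0. On day 3 the lists CDK inhibitors (0.0787) and core pluripotency genes (0.190) lost their call. Cardiac and muscle genes (0.0460) and primitive streak and early mesoderm (0.0475) gained a call on day 0. On day 3 the lists blood and endothelial genes (0.0309), cardiac and muscle genes (0.00154), primitive streak and early mesoderm (0.00698) and Y-linked genes (5.92e-04) gained a call. Fibroblast genes (0.00742), imprinted genes (0.0162), interferon response genes (0.00582) and neuroectoderm and neurons (6.85e-06) gained a call on day 7.

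Without V6.5 WT, imprinted genes (0.187) lost its call on day 3. On day 0 the lists core pluripotency genes (3.47e-04), interferon response genes (0.0364) and Y-linked genes (0.00747) gained a call. CDK inhibitors (0.0231), p53 targets (0.0416), PRC1 components (0.0416) and proliferation genes (0.0494) gained a call on day 7. Trophoblast genes (0.0416) gained a call on day 7.

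Without both WT J1 arrays of day 3, core pluripotency genes (0.0587) lost its call on day 3. On day 3 the lists blood and endothelial genes (0.0498), cardiac and muscle genes (0.00504), p53 targets (0.0434) and primitive streak and early mesoderm (0.0112) gained a call. Y-linked genes (0.0112) gained a call on day 3.

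Without both WT J1 arrays of day 7, fibroblast genes (0.00636), imprinted genes (0.00640), interferon response genes (0.0175) and neuroectoderm and neurons (6.81e-06) gained a call on day 7. Proliferation genes (0.0443) gained a call on day 7.

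When each array was left out in turn, these lists changed sides. Cardiac and muscle genes on day 3 ranged from 0.0182 to 0.266, under 0.05 without KO E14 replicate 2 (0.0313), KO J1 replicate 2 (0.0378), WT J1 replicate 1 (0.0364) or WT J1 replicate 2 (0.0182). CDK inhibitors on day 7 ranged from 0.0271 to 0.193, under 0.05 without KO J1 replicate 2 (0.0271), WT J1 replicate 2 (0.0450) or WT V6.5 replicate 1 (0.0353). Core pluripotency genes on day 0 ranged from 0.0165 to 0.245, under 0.05 without KO E14 replicate 2 (0.0346), WT V6.5 replicate 1 (0.0165) or WT V6.5 replicate 2 (0.0496). Extraembryonic and definitive endoderm on day 7 ranged from 0.0350 to 0.896, under 0.05 without WT J1 replicate 1 (0.0350). Fibroblast genes on day 7 ranged from 0.00200 to 0.285, under 0.05 without KO J1 replicate 1 (0.0171) or WT J1 replicate 1 (0.00200). Hypoxia and glycolysis genes on day 3 ranged from 0.00639 to 0.792, under 0.05 without KO J1 replicate 1 (0.00639). Imprinted genes on day 3 ranged from 0.00622 to 0.0704, over 0.05 without KO E14 replicate 2 (0.0630) or WT V6.5 replicate 1 (0.0704). Imprinted genes on day 7 ranged from 0.0267 to 0.364, under 0.05 without WT J1 replicate 1 (0.0267). Interferon response genes on day 7 ranged from 0.00494 to 0.795, under 0.05 without WT J1 replicate 2 (0.00494). Neuroectoderm and neurons on day 7 ranged from 4.16e-06 to 0.246, under 0.05 without WT J1 replicate 1 (4.16e-06). The p53 targets on day 0 ranged from 6.84e-04 to 0.0894, over 0.05 without KO J1 replicate 2 (0.0894). The p53 targets on day 7 ranged from 0.00773 to 0.193, under 0.05 without KO J1 replicate 1 (0.00773), KO J1 replicate 2 (0.0322), WT J1 replicate 2 (0.0257) or WT V6.5 replicate 1 (0.0353). PRC1 components on day 0 ranged from 0.0165 to 0.0616, over 0.05 without KO J1 replicate 2 (0.0616). Primed epiblast genes on day 7 ranged from 0.0140 to 0.846, under 0.05 without WT J1 replicate 1 (0.0140). Primitive streak and early mesoderm on day 3 ranged from 0.0364 to 0.617, under 0.05 without WT J1 replicate 1 (0.0364). Primitive streak and early mesoderm on day 7 ranged from 0.00335 to 0.0728, over 0.05 without KO E14 replicate 1 (0.0586), WT J1 replicate 1 (0.0728) or WT V6.5 replicate 2 (0.0616). Proliferation genes on day 7 ranged from 0.00105 to 0.357, under 0.05 without KO E14 replicate 1 (0.0222), KO E14 replicate 2 (0.0289) or WT J1 replicate 1 (0.00105). Trophoblast genes on day 7 ranged from 0.0107 to 0.194, under 0.05 without KO J1 replicate 1 (0.0180), KO J1 replicate 2 (0.0107), WT J1 replicate 2 (0.0352) or WT V6.5 replicate 2 (0.0421).

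Weak signals limit the lowest values: 3869 of 19938 genes had all 6 group means under 5.95 on the log2 scale, where changes are compressed.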

Other observations

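Chosen only after the result was seen were the tests on the Dlk1 to Dio3 region and the dilution of fibroblasts, while the test on collagens was set out before its result was seen.

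Lists not taken up above had few or no genes called between KO and WT. Two-cell-like genes, which mark rare ESCs resembling the early embryo, had 0 of 8 called on any day (0 adjusted over the list alone on each), with medians of 0.39, 0.04 and 0.32, and passed on day 0 (adjusted p = 0.0034, and 0.36 with an estimated correlation). Among p53 targets the apoptosis gene Pmaip1 was 1.97 higher on day 7, 1 of 15 (1 adjusted over the list alone, adjusted p = 0.061). That list passed on day 0 with 0 called (0 adjusted over the list alone, adjusted p = 0.0089, and 0.47 with an estimated correlation). Neuroectoderm and neurons had 2 of 25 higher on day 7, the neuronal genes Nefl (1.79) and Stmn2 (1.75) (2 adjusted over the list alone, adjusted p = 0.063). Interferon response genes had 3 of 13 higher on day 7, Ddx58 (1.47), Rsad2 (1.23) and Oasl2 (1.13) (3 adjusted over the list alone, adjusted p = 0.29). Hypoxia and glycolysis genes had 1 of 21 lower, Aldoc at −1.03 (2 adjusted over the list alone, adjusted p = 0.19). Proliferation genes had 0 of 24 called (0 adjusted over the list alone, adjusted p = 0.056 on day 7). Y-linked genes had 0 of 3 called on day 7 (0 adjusted over the list alone, adjusted p = 0.90), with a median of 0.37 while the test pointed down. Oasl2 lost its call with averaged arrays (adjusted p = 0.13), and without KO E14 replicate 2 (0.11), KO J1 replicate 2 (0.071) or either WT V6.5 array (0.085 and 0.088). Aldoc lost its call without KO J1 replicate 1 (0.065) or WT J1 replicate 2 (0.052).

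The noncoding RNAs between Dlk1 and Dio3 are normally expressed from the maternal chromosome. Of 45 measured, 5, 8 and 25 were lower in KO on days 0, 3 and 7 and 0 higher, with medians of −0.41, −0.56 and −1.06, and 22 had a WT mean under 5.95, near the background. The protein-coding genes Dlk1 (0.13, 0.12 and 0.10), Rtl1 (−0.32, −0.36 and −0.35) and Dio3 (0.88, 0.78 and 0.60), chosen after their values were seen, were not called on days 0, 3 and 7.

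Line background as the whole cause and a loss in 1 KO clone only are argued against for the 5 RNAs called on day 0 (Meg3, Rian, DQ267102, Mir380 and Mir377) on the arrays of days 3 and 7, which did not pick them but come from the same clones: their median within J1 was −2.96 or lower (SD between arrays 0.317), and each KO clone lay at least 2.89 below the lower WT line (−2.89, SD 0.301). Over all 45 RNAs the median within J1 was −0.31 or lower on each day (SD 0.118), and the smallest distance of a KO clone below the WT lines −0.64 (SD 0.236). Both lie beyond 2 SD though short of the 2-fold bound first set, and 22 of these RNAs lie near the background. The SDs are between repeat arrays of a line and day and do not measure the spread between lines. The WT lines themselves lay apart, with medians of 5.49, 5.85 and 5.95 in J1 and 6.03, 6.11 and 6.55 in V6.5 on days 0, 3 and 7. The 45 RNAs as a whole therefore do not decide. Stable silencing acquired in culture by both KO clones, apart from Eed, would carry over between days and cannot be told apart from an effect of the genotype, because 4 lines make 3 splits. Loss of Eed may lower these RNAs, but no test here separates the 2.

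The fibroblast list, higher in KO on day 0, may reflect feeder cells. Their abundant collagens Col1a1, Col1a2 and Col3a1 had a median difference of 0.21 on day 0 (SE 0.287 for Col1a1), too close to 0 for its error to tell feeders from expression by the ESCs. The list median went from 0.49 on day 0 to 0.20 on day 3, and of 27 genes above 0 on day 0, 23 had a smaller difference on day 3 but only 12 had shrunk by more than 50%, so a dilution of feeders that do not divide stays open. MEFs had been depleted before EBs were formed, and 1 of the 28 genes is in another list.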
